A study of Homo sapiens with 10 samples.

How the data were processed

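Gene expression was measured by RNA sequencing in 10 libraries described as neural progenitor cells (NPCs) made from H1, an established human embryonic stem cell line. Per the labels, total RNA was taken up in Trizol and 1 µg entered an Illumina TruSeq library preparation. The libraries fall into 5 groups of 2: unedited cells (WT), 2 STAMBP knockout lines (KO1 and KO2), knockout cells given STAMBP (KO+STAMBP) and knockout cells given CFLAR (KO+CFLAR). The labels do not say which knockout line received a construct, nor whether the libraries of a group came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

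The authors deposited whole-number read counts per gene, without normalization, for 60898 rows. The submitters' processing notes name fastp 0.20.0, RSEM 1.2.4 and DESeq2, and the builds hg38 and GRCh38, with no role or order. RSEM estimates counts that need not be whole, and whether the deposited counts were rounded is not given in the sources used here; neither are the annotation release and the strand setting. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. Of the rows, 8314 carry a locus name beginning with MSTRG, and 667 of these have no Ensembl identifier. Those 667 held 0.33% of all counts and stayed in the tests. The total was 16495116 to 20832700 counts per library. A count of 0 in a library allows a level of up to 0.144 to 0.182 counts per 1000000 counts (CPM), taking 3 counts as the floor. These floors, and the 95% intervals given for genes with 1 to 3 counts in a group, cover counting error only.

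From the deposited counts, a quasi-likelihood model was fitted with edgeR 4.0.16 in R 4.3.3, with TMM factors and a mean for each of the 5 groups over all 10 libraries, which leaves 5 residual degrees of freedom. The filterByExpr filter kept 21063 genes, which held 99.9% of the counts. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. A log2 fold change is given with its standard error (SE), taken as the size of the change divided by the root of the F statistic. In KO vs WT, the KO1 and KO2 means had equal weight. The rescue groups were compared with that same knockout mean, with WT and with each other. A gene counted as restored when it was called in both knockout lines in a shared direction and called the opposite way in rescue vs KO. The restoration slope is the slope through the origin of the rescue vs KO log2 change on the KO vs WT log2 change over those genes.

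Gene lists, 26 in number, were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation. Over-representation of apoptosis-related genes was tested with a one-sided Fisher's exact test against all tested genes. The genes named below follow a rule also fixed before the data were examined. It takes STAMBP and CFLAR, the 10 largest rises and 10 largest falls among genes changed in both lines, up to 4 genes per list by adjusted p, 6 rises and 6 falls per rescue and up to 5 each way between the lines. The rises and falls need a mean of at least 2 CPM and a gene symbol that is not a clone name. Some genes that the rule takes are not reported here. Genes named outside the rule are marked as chosen after their values were seen. Positions come from GENCODE release 29 on GRCh38, in which 57973 of the 60231 Ensembl identifiers were found.

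The fit was tested on simulated counts, in 5 draws per comparison with 200 changed genes each. For KO vs WT it recovered 36% of changes of 1.25-fold, 71.2% of 2-fold and 80.8% of 4-fold. For KO1 vs KO2 it recovered 26.4%, 58% and 75.2%. False calls made up 8.41% of the calls for KO vs WT, 9.47% for KO+CFLAR vs KO and 8.8% for KO1 vs KO2, above the nominal 5%. All other genes were simulated at WT levels in every group, and changed genes that the filter removed counted as not recovered. The real KO vs WT called 16055 of 21063 genes, so its recovery and false share may differ from these rates. The same holds for the rescues against the knockout. A simulated list of shifted genes was called and 0 of 20 random lists were. Because comparisons share libraries, 20 simulations with no effect and 20 with a knockout effect but no rescue effect were run to show what shared libraries alone give.

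Alternatives fixed before the data were examined were DESeq2 1.42.0, median-of-ratios factors, no filter on low counts, a filter of at least 50 counts in at least 2 libraries, the replicate number as a block, each library left out, only the groups compared, each knockout line alone as the baseline, and different lines for calling and for measuring. Library size alone as the scaling, the fit without the libraries labelled KO+CFLAR, protein-coding genes by GENCODE type, and separate control libraries for comparisons that share controls were added after the data were seen. The planned filter on the gene type given in the file was not run, since the table has no such column. The leave-one-out fits kept the 21063 genes; that was decided after a first run, in which a group of 1 library loosened the filter to between 21776 and 22141 genes.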

Results

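RNA of 10 NPC libraries was sequenced to ask what loss of STAMBP, a deubiquitinase that acts on endosomal sorting, changes in neural progenitors, and how far added STAMBP or CFLAR, an inhibitor of caspase-8 activation, returns expression towards WT. Each of the 5 groups has 2 libraries of 16495116 to 20832700 counts. Levels below are mean CPM ± SD, with n = 2 for WT and for each rescue and n = 4 for the knockout libraries KO1 and KO2 together. Library pairs within a group differed by 1.95 to 3.59 chi-square units per gene, above counting noise, so no library was counted as a duplicate.

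The targeted genes were examined first. STAMBP (ENSG00000124356, chromosome 2, 73828916 to 73873659, GRCh38) was at 45.3 ± 2.7 CPM in WT and 18.6 ± 1.2 CPM in the knockout libraries, a log2 change of -1.28 ± 0.07 (SE, adjusted p = 6.7e-10). It was at 42.9 ± 3.4 CPM in KO+STAMBP. In the libraries labelled KO+CFLAR, STAMBP was at 41.5 ± 2.0 CPM, 1.15 ± 0.07 above the knockout on the log2 scale (adjusted p = 2.0e-09), and -0.13 ± 0.08 from WT (adjusted p = 0.236). CFLAR (ENSG00000003402, chromosome 2, 201116104 to 201176687) rose 7.90-fold in the knockout, from 32.3 ± 2.7 to 254 ± 8.1 CPM (log2 2.98 ± 0.05, adjusted p = 1.28e-15). It was at 32.1 ± 0.04 CPM in KO+STAMBP and at 30.4 ± 1.4 CPM in the libraries labelled KO+CFLAR, -0.08 ± 0.07 from WT (adjusted p = 0.418). The libraries labelled KO+CFLAR thus show neither the lower STAMBP level of the knockout lines nor a CFLAR level above WT. STAMBP in KO+STAMBP was not above WT either (log2 -0.08 ± 0.08, adjusted p = 0.473). Whether reads of either construct are counted is not known. Every direction given below for KO+STAMBP and for the libraries labelled KO+CFLAR rests on their labels.

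**Figure D1:**
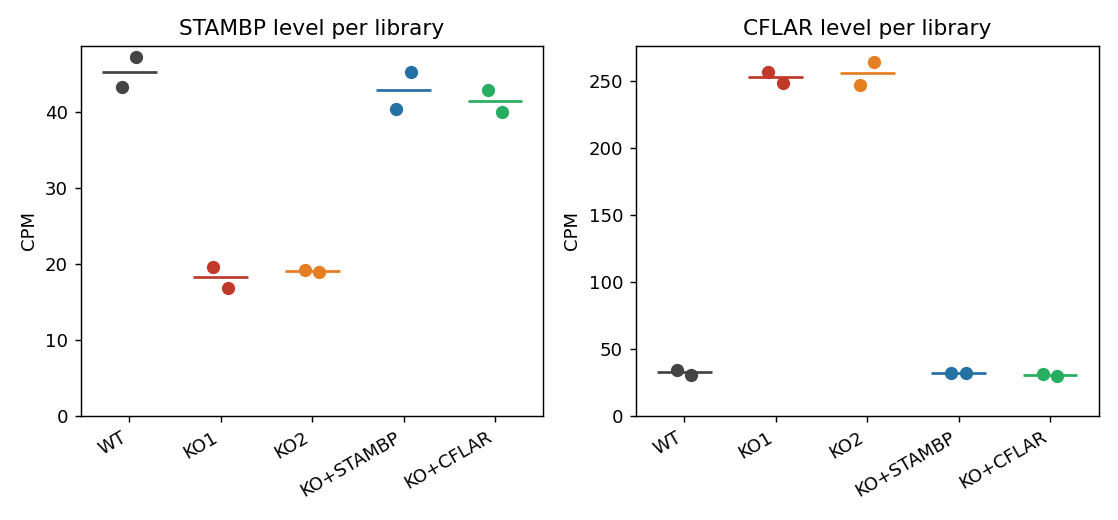
Level of STAMBP (left) and CFLAR (right) in CPM in each library, with points for libraries and bars for group means of 2. The libraries labelled KO+CFLAR lie at 41.5 CPM for STAMBP and 30.4 CPM for CFLAR, against 45.3 and 32.3 CPM in WT.

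The first principal component held 87.9% of the variance and placed the knockout libraries at 178 to 180, with WT and both rescues at -112 to -124. The second held 4.23% and placed WT at -61.6 and -56.5, away from both rescues at 24.8 to 30.9.

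**Figure D2:**
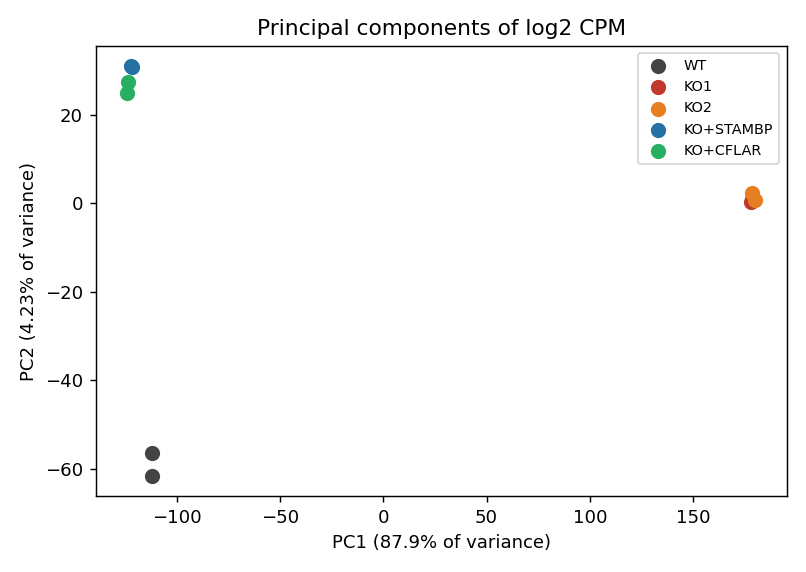
Principal components of log2 CPM, a point per library coloured by group. The 4 knockout libraries lie at 178 to 180 on the first component, and the other 6 lie between -112 and -124.

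Loss of STAMBP was examined in KO vs WT. Most epithelial genes on the list rose and most neural genes fell. Of 22 measured epithelial and non-neural ectoderm genes, 21 rose and 0 fell (median log2 7.45, camera adjusted p = 4.24e-39). With an estimated correlation the list had adjusted p = 0.0109. The keratins KRT8 and KRT18 rose from 15.2 ± 0.05 to 2557 ± 87 CPM and from 5.69 ± 0.88 to 1332 ± 26 CPM, and the tight junction gene CLDN4 from 1.74 ± 0.16 to 1065 ± 20 CPM. Of 37 neuron genes, 34 fell and 3 rose (median -3.91, adjusted p = 3.52e-31, and adjusted p = 0.0133 with an estimated correlation). DCX, a microtubule-binding protein of migrating neurons, went from 504 ± 26 to 1.82 ± 0.44 CPM. TBR1, a transcription factor of deep cortical neurons, went from 378 ± 10 to 1.44 ± 0.33 CPM. In the model, 16055 of 21063 genes were called, 7750 higher and 8305 lower, of which 4209 and 5070 changed at least 2-fold. Scaled by library size alone, chosen after seeing the data, 6646 of 16096 called genes were higher.

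Among genes changed in both lines, the largest rises included SPRR2A, a cornified envelope protein, at 198 ± 10 CPM in the knockout with 0 counts in WT, at least 2483-fold higher. MIR205HG was at least 1066-fold, OVOL1 at least 659-fold, CXCL1 at least 578-fold and CASP4 at least 502-fold higher, and TOR4A and TMEM40 were at least 740-fold and 694-fold higher. KRT7 was at 351 ± 12 CPM in the knockout and had 1 count in WT, and the complement gene C3 rose from 0.127 ± 0.097 to 846 ± 29 CPM. The largest falls were NEUROD6, with 149.9 ± 5 CPM in WT and 1 count in the knockout, RHBDL3, at least 906-fold lower, PANTR1, LINC00461, FABP7, NDP, NEUROD1, NCAN, ACTL6B and SLA. FABP7, a fatty acid binding protein of radial glia, went from 1124 ± 41 to 0.446 ± 0.24 CPM, and NCAN, a neural proteoglycan, from 732 ± 4.3 to 0.504 ± 0.13 CPM.

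Among neural lists, 25 of 30 neural progenitor genes fell and 4 rose (median -1.96, adjusted p = 9.25e-23, and adjusted p = 0.00656 with an estimated correlation). PTPRZ1 fell from 1882 ± 81 to 3.71 ± 0.70 CPM and SLC1A3 from 704.5 ± 5.6 to 40.02 ± 2.8 CPM. Of 23 forebrain and midbrain genes, 18 fell and 2 rose (median -3.76, adjusted p = 8.66e-10, and adjusted p = 0.0487 with an estimated correlation), among them FEZF2, EMX1 and EMX2. Of 20 glia genes, 12 fell and 5 rose (median -1.36, adjusted p = 0.0172, and adjusted p = 0.057 with an estimated correlation); NFIA and SLC1A2 fell and CD44 rose. Not all progenitor genes fell: PAX6 and VIM, chosen after their values were seen, were at 115% and 105% of WT. SOX1 and SOX2, chosen in the same way, were at 0.325% and 9.56%. Of 37 neural list members at 100 CPM or more in WT, 20 lay below 10% of WT and 9 above 50%. Of 3 measured hindbrain genes 2 rose and 1 fell, and the list was not called (adjusted p = 0.739). The knockout and WT libraries thus differ in cell-type markers. The pathway lists below compare such libraries, and a response within progenitor cells was not tested apart from that difference.

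All 34 cell cycle genes fell (median -2.72, adjusted p = 7.33e-25); MKI67 went from 382 ± 14 to 22.4 ± 2.0 CPM and TOP2A from 463 ± 1.6 to 32.4 ± 0.96 CPM. All 30 p53 target genes rose (median 1.69, adjusted p = 6.15e-14), including CDKN1A, an inhibitor of cyclin-dependent kinases, from 60.3 ± 2.9 to 1635 ± 20 CPM, and PERP. All 24 NF-κB targets rose (median 5.42, or 5.27 with genes at 3 counts or fewer set to their bound; adjusted p = 3.22e-13), with BIRC3 at 0.287 ± 0.077 and 125 ± 3.2 CPM. Of 31 interferon genes 28 rose and 2 fell (median 2.56, adjusted p = 1.45e-09); HLA-C went from 29.9 ± 0.11 to 986 ± 16 CPM. Of 26 genes of the unfolded protein and integrated stress responses 24 rose and 1 fell (median 1.49, adjusted p = 1.05e-09), including ATF3 and SLC7A11. With an estimated correlation, the camera adjusted p was 0.0163 for cell cycle, 0.011 for p53 and 0.0215 for NF-κB genes. It was 0.0109 for interferon and 0.0147 for stress response genes.

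Genes of cell death were the study's stated interest. Of 59 apoptosis-related genes 41 rose and 13 fell in KO vs WT (median 0.96, adjusted p = 2.19e-06). In both lines 41 were higher, 69.5% against 33.9% of all tested genes (odds ratio 4.47, one-sided Fisher's exact p = 2.43e-08); 11 were lower in both (p = 0.998). The list joins the 3 lists that follow, so its result and theirs rest on the same genes. It holds genes that promote death and genes that oppose it. Some are also on lists given above, among them FAS and TNFRSF10B (p53 targets) and BIRC3 (NF-κB targets). Of 15 death receptor genes 12 rose and 3 fell (median 2.17, adjusted p = 2.87e-05), with FAS at 2.73 ± 0.15 and 41.9 ± 2.2 CPM and TNFRSF10B, a TRAIL receptor, at 72.7 ± 2.4 and 496 ± 3.6 CPM. Of 25 mitochondrial apoptosis genes 14 rose and 7 fell (median 0.35, adjusted p = 0.0119), with BMF, PMAIP1, BIK and BCL2L11 among those that rose. Of 19 survival genes 15 rose and 3 fell (median 1.30, adjusted p = 0.00327); BCL2L1 and MCL1 rose and BIRC5 fell. These 3 lists had adjusted p = 0.0473, 0.0487 and 0.0413 with an estimated correlation, and the joined list had adjusted p = 0.0124.

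Of 32 ESCRT and endosome genes 26 rose and 5 fell (median 0.57, adjusted p = 0.00213, and adjusted p = 0.0487 with an estimated correlation), among them CHMP1B, CHMP4C, VPS4B and RAB7A. Of 30 autophagy and lysosome genes 28 rose and 1 fell (median 1.22, adjusted p = 6.29e-09), with SQSTM1 at 101.06 ± 3.4 and 1428 ± 15 CPM. Hypoxia and glycolysis genes rose in 20 of 25 and fell in 1 (median 1.24, adjusted p = 2.84e-09). Neural crest and mesenchyme genes rose in 18 of 27 and fell in 7 (median 2.12, adjusted p = 2.87e-05), with COL1A1 at 6.64 ± 0.09 and 1030.3 ± 25 CPM. TGF-β and BMP targets rose in 18 of 23 and fell in 5 (median 1.52, adjusted p = 0.000154). With an estimated correlation, the camera adjusted p was 0.011 for autophagy and lysosome genes and 0.0119 for hypoxia and glycolysis genes. It was 0.0133 for neural crest and mesenchyme genes and 0.0423 for TGF-β and BMP targets. WNT genes fell in 15 of 23 and rose in 6 (median -1.08, adjusted p = 0.043, and adjusted p = 0.0848 with an estimated correlation). Camera called the WNT list in neither line singly (adjusted p = 0.0558 for KO1 vs WT and 0.0714 for KO2 vs WT). As sets, pluripotency (adjusted p = 0.172), endoderm and mesoderm (0.687), Notch (0.451), MAPK feedback (0.225) and mitochondrially encoded genes (0.687) were not called by camera. Their members did change: 9 rose and 3 fell of 14, 12 and 4 of 17, 7 and 11 of 19, 9 and 12 of 21, and 3 and 6 of 13. The MAPK list had a median of -0.83 and a mean of 0.14. The planned fry test, which does not set a list against other genes, called each of these lists (fry adjusted p from 2.12e-08 to 0.0152). Adjusted over the list alone, the counts were the same except for neural progenitor genes, of which 5 rose.

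**Figure D3:**
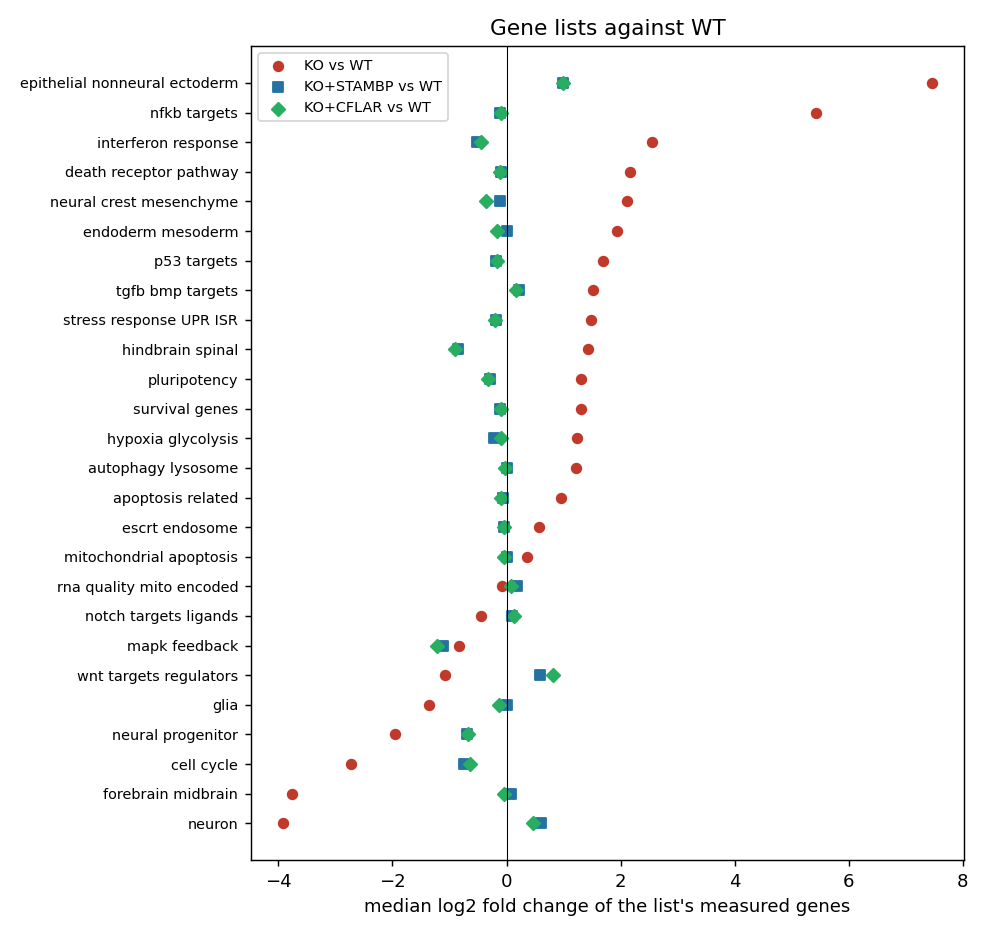
Median log2 fold change against WT of the measured genes in each of the 26 lists, for the knockout (circles), KO+STAMBP (squares) and the libraries labelled KO+CFLAR (diamonds). The epithelial list lies at 7.45 and the neuron list at -3.91 in the knockout.

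The lines were also compared with WT singly. KO1 vs WT called 15357 genes and KO2 vs WT 15394, of which 7134 were higher and 7357 lower in both and 3 went opposite ways. Independent lists of these sizes would share 2684 and 2930. Simulations without effect gave an overlap of 0 to 2 genes and a correlation of 0.479, against 0.96 observed. The covariance was 5.83 against a simulated 0.125, a difference of 5.70. With a separate WT library for each line, a split chosen after seeing the data, 13077 or 13081 genes were shared in direction, with 9 or 13 opposite and a covariance of 5.86 or 5.83. Each WT library then stands alone and is assumed to vary like the other groups. A deviation that both WT libraries share would remain in either check.

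KO1 differed from KO2 in 33 genes, 28 higher and 5 lower, with 1196 at an unadjusted p under 0.05. JPH4, a junctophilin, was at 1.72 ± 0.13 CPM in KO1 and had 1 count in KO2 (ratio 56.1, 95% interval 9.69 to 2256), against 75.2 ± 0.62 CPM in WT. KIF20B and CENPF, which act in mitosis, were higher in KO1 by 0.95 ± 0.11 and 0.69 ± 0.07 on the log2 scale (adjusted p = 0.00118 and 0.000239), and ZMYM6 was lower by -0.98 ± 0.13 (adjusted p = 0.00418). The count was 59 without KO1 replicate 2, 20 without KO2 replicate 2 and 251 without the low-count filter, with 29, 17 and 144 of them higher in KO1, so the excess of higher genes was absent without KO1 replicate 2.

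The KO+STAMBP libraries were compared with the knockout. Most neuron genes rose and most epithelial genes fell. Of 37 neuron genes 34 rose and 2 fell (median 4.78, adjusted p = 2.0e-38). Of 22 epithelial genes 21 fell and 1 rose (median -6.66, adjusted p = 9.72e-35). With an estimated correlation, the camera adjusted p was 0.005 for neuron and 0.000941 for epithelial genes. Of 30 neural progenitor genes 19 rose and 10 fell (median 1.17). NEUROD6 was at 668.6 ± 16 CPM and TTR, the transthyretin gene, at 329.7 ± 2.5 CPM, each with 1 count in the knockout; RHBDL3, LINC00461, SLA and ACTL6B completed the largest rises. The largest falls were IL32, CXCL1, SPRR2A, TMEM265, ZNF750 and MLPH. Of 34 cell cycle genes 33 rose (median 2.02), all 30 p53 targets fell (median -1.88) and all 24 NF-κB targets fell (median -5.52, or -5.24 at the bound). Of 59 apoptosis-related genes 42 fell and 12 rose (median -1.33, adjusted p = 4.91e-07, and adjusted p = 0.005 with an estimated correlation). In all, 8441 genes were higher and 7962 lower. This near-even split depends on the scaling: by library size alone, chosen after seeing the data, 9836 of 16544 called genes were higher.

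The libraries labelled KO+CFLAR gave 8423 higher and 8011 lower genes against the knockout, or 9782 higher of 16585 by library size alone. Neuron genes rose in 34 of 37 and fell in 3 (median 4.77, adjusted p = 1.67e-36), and epithelial genes fell in 21 of 22 (median -6.82, adjusted p = 5.2e-35). With an estimated correlation, the camera adjusted p was 0.00456 for neuron and 0.000923 for epithelial genes. Of 30 neural progenitor genes 19 rose and 10 fell (median 1.30). All 30 p53 targets fell (median -1.81). Of 59 apoptosis-related genes 43 fell and 12 rose (median -1.39, adjusted p = 3.66e-07, and adjusted p = 0.00454 with an estimated correlation). NEUROD2 joined the largest rises and S100A9, TMPRSS11E and EPSTI1 the largest falls. Both rescues changed 7963 genes up and 7540 down relative to the knockout, where independent lists would share 3376 and 3028; they share the knockout libraries, and 6 genes went opposite ways. The covariance of their changes was 5.94 against a simulated 0.0698. With a separate knockout line for each rescue, also chosen after seeing the data, 14463 or 14490 genes were shared in direction and the covariance was 5.82.

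Of the 14491 genes changed in both knockout lines, 13391 (92.4%) were restored in KO+STAMBP and 13462 (92.9%) in the libraries labelled KO+CFLAR, with slopes of -0.956 and -0.961. Simulations with a knockout effect and no rescue gave 0 to 3 restored genes and a mean slope of -0.0136. When genes were called in one knockout line and measured against the other, 87.4% to 88.3% were restored. Of the restored genes, 8017 in KO+STAMBP did not differ from WT by the test, 2180 stayed on the knockout side of WT and 3194 went past it; for the libraries labelled KO+CFLAR these were 8138, 1998 and 3326.

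**Figure D4:**
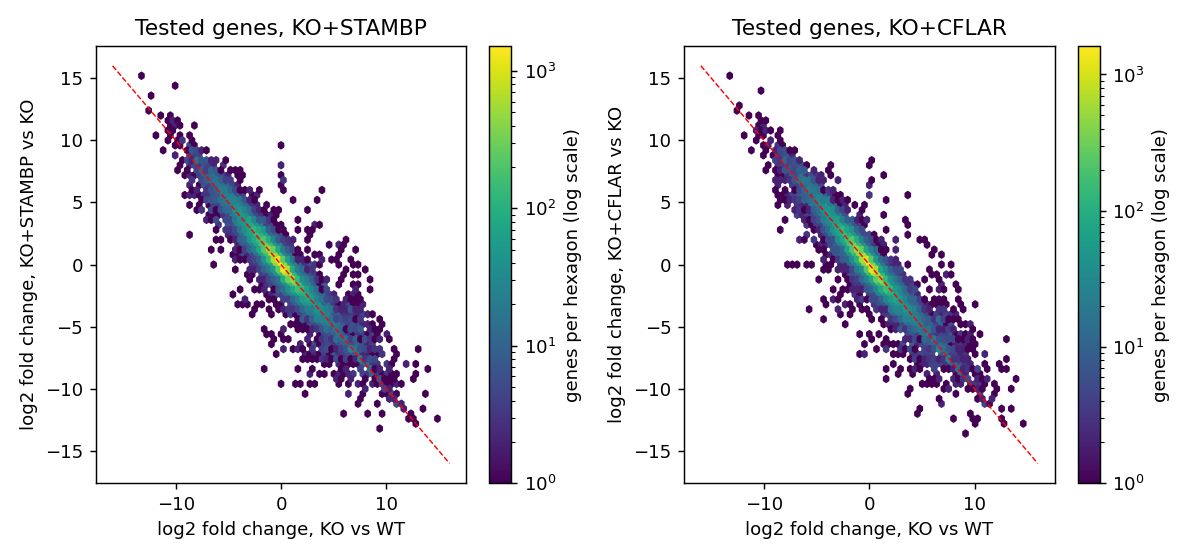
Log2 fold change of rescue vs knockout (y) against knockout vs WT (x) for 21063 tested genes, as counts per hexagon on a log colour scale; the dashed line marks full reversal. The slopes over genes changed in both lines were -0.956 for KO+STAMBP and -0.961 for the libraries labelled KO+CFLAR.

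The rescues were also compared with WT. Feedback genes of the MAPK pathway were lower than WT in 17 of 21 in KO+STAMBP and in 17 of 21 in the libraries labelled KO+CFLAR, and 0 were higher (medians -1.11 and -1.22, adjusted p = 1.06e-80 and 1.02e-91). SPRY4, an inhibitor of receptor tyrosine kinase signalling, was at 355.2 ± 0.7 CPM in WT, 5.75 ± 0.04 in KO+STAMBP and 5.08 ± 0.13 in the libraries labelled KO+CFLAR, against 34.2 ± 1.4 in the knockout. SPRY1 was at 249 ± 3.0 CPM in WT and at 37.9 ± 0.74 and 33.2 ± 1.7 in the rescues. Neural progenitor genes were lower in 23 and 22 of 30 (medians -0.70 and -0.67) and cell cycle genes in 34 and 33 of 34 (medians -0.74 and -0.63), while neuron genes were higher in 22 and 20 of 37 (medians 0.60 and 0.47) and WNT genes in 14 and 13 of 23 (medians 0.58 and 0.82). These 5 lists were called in both rescues with an estimated correlation too. Epithelial genes stayed above WT in 9 and 11 of 22 and below in 1 (medians 0.99 and 0.99, or 0.93 and 0.86 at the bound, adjusted p = 0.0126 and 0.0255, and 0.0868 and 0.0982 with an estimated correlation). Other lists were called at the preset correlation alone. Stress response genes were lower in 12 and 12 of 26 and higher in 3 and 1, and interferon genes lower in 14 and 14 of 31 and higher in 3 and 2. Hypoxia and glycolysis genes were lower in 12 and 11 of 25 and higher in 7 and 5. Endoderm and mesoderm genes were called higher by camera, with 2 and 2 of 17 higher and 4 and 3 lower. The p53 targets were lower in 12 and 14 of 30 and higher in 3 and 2 (medians -0.18 and -0.18, adjusted p = 0.0592 and 0.0104). Mitochondrially encoded genes were higher in 11 and 2 of 13 (adjusted p = 0.0352 and 0.326), and TGF-β and BMP targets higher in 11 and 9 of 23 and lower in 3 and 5 (adjusted p = 0.0352 and 0.394). KO+STAMBP differed from WT in 7354 genes and the libraries labelled KO+CFLAR in 7104; 5888 were shared in direction and 2 were opposite, where independent lists would share 545 higher and 700.1 lower against 2718 and 3170 observed. Both rescues share the WT libraries, and simulations without effect gave a covariance of 0.123 against 0.533. With a separate WT library for each rescue, the covariance was 0.373 or 0.388. Both checks cover only the spread between libraries. A deviation that both WT libraries share would remain in them, so whether these differences belong to the rescues or to WT stays open.

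The libraries labelled KO+CFLAR differed from KO+STAMBP in 229 genes, 132 higher and 97 lower; by library size alone 108 of 230 were higher, so the majority direction depends on the scaling. Cell cycle genes were higher in 6 of 34 (median 0.15, adjusted p = 3.82e-16), with MKI67 at 207 ± 6.8 against 165 ± 6.9 CPM, and TGF-β and BMP targets were lower in 2 of 23 and higher in 1 (median -0.24, adjusted p = 1.28e-06, and adjusted p = 0.0468 with an estimated correlation). Of 59 apoptosis-related genes 0 differed by edgeR (adjusted p = 0.389 for the list). The count fell to 26 without KO+STAMBP replicate 1 or replicate 2 and to 53 without KO+CFLAR replicate 1. It was 364 by DESeq2 and 780 without the low-count filter.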

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

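The tests in this part were chosen after the results were seen, except for the comparison of the 3 pairings of the knockout libraries, which was fixed before its result was known.

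The direct test between the knockout lines flagged 7 named genes, as log2 of KO1 over KO2: JPH4 5.53, ZNF395 1.97, CCDC39 1.36, KIF20B 0.95, NPTX1 0.92, CENPF 0.69 and ZMYM6 -0.98. All but CENPF were named because this same test had called them, so their flags were fixed by the naming rule. The table holds more than 1 row under the symbol CCDC39, so its reads could be split, and the JPH4 value is fitted from 1 count in KO2 (interval of the ratio 9.69 to 2256). ZNF395 was not called by DESeq2 (log2 1.99, adjusted p = 0.143) and NPTX1 not with the replicate block (adjusted p = 0.0528). Of the 10 fits without a library, the call was lost in 8 for NPTX1, 6 for ZNF395 and 3 for CCDC39, with the direction kept in each. The pluripotency list (median 0.13, adjusted p = 0.0428) and the mitochondrially encoded list (median -0.0742, adjusted p = 0.00062) also differed, both with adjusted p = 0.67 with an estimated correlation.

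The direct test between the libraries labelled KO+CFLAR and KO+STAMBP flagged 18 named genes. Higher in the libraries labelled KO+CFLAR on the log2 scale were ZNF395 by 3.74, SFRP1 by 0.41, MKI67 by 0.33, CENPF by 0.32, SLC1A3 by 0.29, HES6 by 0.28, TOP2A by 0.26, EOMES by 0.23 and ID4 by 0.17. Lower were COL1A2 at -0.41, KRT18 at -0.39, SFRP2 at -0.30, CDKN1A at -0.30, MT-ND6 at -0.27, CCND1 at -0.24, RSPO2 at -0.23, FN1 at -0.21 and SQSTM1 at -0.19. By list medians, cell cycle (0.15), Notch (0.0689) and neural progenitor genes (0.0391) were higher. TGF-β and BMP (-0.24), WNT (-0.16), neural crest and mesenchyme (-0.13), MAPK feedback (-0.13), mitochondrially encoded (-0.10), stress response (-0.10), autophagy and lysosome (-0.0837), p53 (-0.0548) and glia genes (-0.0241) were lower. With an estimated correlation the calls held for cell cycle, neural progenitor, Notch, MAPK feedback and TGF-β and BMP genes.

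The first pattern is the fall of neural and rise of epithelial genes in the knockout libraries. Scaling was not the whole cause: by library size alone the neuron median was -4.09 and the epithelial median 7.28. A mixture with at least 10% of cells like WT would bring their abundant transcripts, but 20 of 37 neural list members at 100 CPM or more in WT lay below 10% of WT; a first form of this test, on the neuron list's summed CPM (15.6% of WT) and median ratio (6.81%), had fallen between its bounds. Whether the knockout libraries came from cells of another source cannot be told apart from the knockout, since STAMBP was lower by -1.28 either way. An effect of STAMBP loss stays open. It needs a return towards WT with added STAMBP, and 13391 of 14491 genes were restored in KO+STAMBP; rescue libraries from WT-like cells would give that too, and no value here separates these.

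The second pattern is WT-like STAMBP and CFLAR in the libraries labelled KO+CFLAR. A swap of labels with KO+STAMBP predicts raised CFLAR there, and its log2 change against WT was -0.0025. That counts against a swap only if reads of the construct are counted, which no library shows, so whether labels were swapped stays open. STAMBP was at 42.9 CPM in KO+STAMBP and 41.5 CPM in the libraries labelled KO+CFLAR, against 18.6 CPM in the knockout libraries. Whichever of these groups received CFLAR, its STAMBP level was above the knockout. These values argue against a swap as the cause of the WT-like STAMBP level, and do not address CFLAR. Rescued cells that kept the knockout lines' lower STAMBP transcript would match the knockout, and STAMBP was 1.15 above it. Reads of the construct missing from the counts may explain CFLAR, at -0.082 against WT, but would not by themselves raise STAMBP. STAMBP was, however, among the 13462 of 14491 genes restored in the libraries labelled KO+CFLAR. Whether its level only followed that wider return was not tested, so it need not point to a label exchange. The libraries labelled KO+CFLAR differed from KO+STAMBP by 4.24 to 6.66 chi-square units per gene, against 46.5 to 50.1 from WT. These values argue against a label exchanged with an outside sample unlike KO+STAMBP. No table holds construct reads, so missing reads and a label exchanged with a sample like KO+STAMBP cannot be told apart.

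The third pattern is the likeness of KO1 and KO2, whose libraries differed by 2.47 to 4.18 chi-square units per gene, against 3.35 and 3.09 within the lines. With 1 source behind both lines, pairing the libraries otherwise should call as many genes, and the pairing by line called 33 against 2 and 0 for the others; 3 pairings are too few for a share under 0.05. At an unadjusted p under 0.05 the pairing by line had no such excess, with 1196 genes against 1213 and 1052. Gene length may account for part of the 28 genes higher in KO1: their median longest transcript was 7948 bases, at percentile 100 of 10000 random sets matched on CPM (median 4114). Without KO1 replicate 2, 29 of 59 called genes were higher in KO1, so the excess in that direction depends on that library, and the length test was not repeated without it. A length-dependent difference between preparations of the lines would also part them without separate sources, so the pairing test argues against a single source only as far as the adjusted calls go and are not of that kind. The lines did differ in the direct test; whether that is biological stays open, as untested.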

How the results depend on the processing

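Values of gene lists here are -log10 of the adjusted p, signed by direction. By DESeq2, KO+CFLAR vs KO+STAMBP had 364 genes, and the slopes were -0.96 for STAMBP and -0.965 for CFLAR. Without the low-count filter there were 251 genes for KO1 vs KO2 and 780 for KO+CFLAR vs KO+STAMBP, with slopes of -0.939 and -0.945. In that setting the endoderm and mesoderm list reached 1.58 in KO vs WT and turned to -1.88 (KO+STAMBP vs KO) and -1.91 (KO+CFLAR vs KO), from uncalled values of the other sign; pluripotency reached -1.74 and -2.05, mitochondrially encoded genes 2.86 and 1.70, and glia fell to 0.885 and 0.605. The stricter filter gave slopes of -0.974 and -0.981, and a WNT value of -1.19 in KO vs WT. With an estimated correlation, glia had -1.24 (KO vs WT), 1.19 and 1.14 (the rescues), and WNT -1.07. With calling and measuring lines apart, the slopes were -0.922 and -0.915 for STAMBP and -0.928 and -0.921 for CFLAR. Fewer libraries then enter each axis, and the genes are the 15357 or 15394 called in 1 line. The cause was not tested for any change in this paragraph.

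Leaving out each library gave 20 to 59 genes for KO1 vs KO2, 26 to 311 for KO+CFLAR vs KO+STAMBP, slopes of -0.969 to -0.907 (STAMBP) and -0.974 to -0.912 (CFLAR), with the weakest slopes without WT replicate 2, and WNT values of -1.56 to -1.19. A library left alone in its group is assumed to vary like the others. The odds ratio for apoptosis-related genes was 4.42 to 4.93, or 4.69 to 5.33 when the filter was reapplied, since more genes were then tested. Library size alone, chosen after seeing the data, moved the median of KO vs WT to -0.22 and split KO+CFLAR vs KO+STAMBP into 108 higher of 230. Without the libraries labelled KO+CFLAR, also chosen after seeing the data, KO vs WT had 15916 genes and 13335 were restored in KO+STAMBP. With protein-coding genes alone these were 13124 and 11291.

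Deviations of same-numbered libraries correlated at -0.0209 to 0.0719 over 10 pairs of groups, 0 of them above 0.1. The highest value was between KO1 and KO2. On the third principal component (1.42% of the variance), replicate 1 lay at -36.2 in KO1 and -21.2 in KO2. Replicate 2 lay at 26.5 and 31.0, and the libraries of the other groups lay between -2.32 and 3.34. A step shared by same-numbered knockout libraries is therefore not excluded. All 10 libraries correlated best with their own number. The 2 libraries of a group deviate from their mean by equal and opposite amounts, however, so each group gives only a single outcome. With the replicate block, KO vs WT had 16036 genes, KO1 vs KO2 had 30 and KO+CFLAR vs KO+STAMBP had 301.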

Other observations

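Some named genes differed from WT in both rescues. TTR, a transthyretin gene that choroid plexus expresses strongly, was at 19.1 ± 1.1 CPM in WT, 329.7 ± 2.5 in KO+STAMBP and 292 ± 6.6 in the libraries labelled KO+CFLAR. RSPO2, a secreted enhancer of WNT signalling, was at 18.9 ± 0.76, 142.7 ± 0.35 and 121.3 ± 1.1 CPM, and NEUROD6, a transcription factor of cortical neurons, at 149.9 ± 5.0, 668.6 ± 16 and 593 ± 0.86 CPM. SLC1A3, a glutamate transporter of radial glia and astrocytes, was lower, at 704.5 ± 5.6, 180.5 ± 2.2 and 221 ± 6.2 CPM, as was FABP7, at 1124 ± 41, 228 ± 3.3 and 241 ± 3.8 CPM.

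The paralog STAMBPL1 fell with STAMBP in the knockout (log2 -1.33 ± 0.19, adjusted p = 1.28e-05) and was above WT in KO+STAMBP by 0.54 ± 0.19 (adjusted p = 0.0382) and in the libraries labelled KO+CFLAR by 0.66 ± 0.18 (adjusted p = 0.0125). It was chosen after its values were seen, and reads of the paralogs could be shared in the counting, which was not tested.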
